A study of Zea mays with 8 samples.

How the data were processed

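The samples were 8 RNA sequencing libraries from leaf 6 of maize B73, with 2 libraries for each of 4 groups formed by nitrogen supply and leaf zone. The deposited table lists values per assembled locus and library, which were read as FPKM, a unit judged from the values because neither header nor labels state it: they are not whole numbers, column totals differ, and the shortest loci hold the highest values. According to the submitters' processing notes, TopHat2 and edgeR were used with the genome build B73 RefGen_v3; their versions and roles, the normalisation and the read numbers are not given in the sources used here. No genome sequence of that build was used here, and positions are those of the table.

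The table's 44070 lines described 43110 loci, since 865 loci carry several gene identifiers on repeated lines with equal values, and each locus was kept once. Of all loci, 4993 share a span with another locus and 4137 have no gene identifier. Gene names came from a RefSeq gene table of a later assembly, matched by identifier alone: 18160 loci matched, 413 of them to 2 or more genes, and 2712 received an informative name. Of the 24706 loci tested, 2067 were named and 821 carry several identifiers, so most results concern loci without a name.

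Choices of test, comparisons, gene lists, the naming rule and most variations of the procedure were made before the data were examined. The plan assumed read counts and a quasi-likelihood test; because the table holds FPKM, the fallback written with the plan was used, limma with an intensity trend on log2(FPKM + 1). Loci with a mean of at least 1 FPKM in at least 1 group were tested in a model of 4 group means with 4 residual degrees of freedom, and p values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The 5 comparisons were low against high nitrogen in each zone, elongation against division zone at each supply, and the difference between the nitrogen responses. Labels give replicate numbers 1 and 2 in every group without saying that a number marks a shared plant or batch, so the model had no block for it.

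Gene lists for hormones, cell cycle, cell wall, nitrogen metabolism, photosynthesis and other themes were planned as 38 lists, of which 6 were dropped for too few names and 32 were kept; 3 were added after the data were seen, for tubulins, benzoxazinoids and plastid gene names. The 31 lists with at least 3 tested members, 28 of them planned, were tested by camera with a preset correlation of 0.01. Genes named in the text were taken by rule: the 5 largest called rises and falls per nitrogen comparison and the 3 largest for zones and interaction, with both libraries separated and at least 5 FPKM in the higher group; up to 4 called members per list by p, or 2 uncalled ones by level; and every tested gibberellin biosynthesis gene. Genes with uninformative names were passed over. Outside the rule, lox6, D8, HK1, NF-YA4, NF-YA11, BX14, KN-1, the untested CPPS2 and ga3ox2 and, in the division zone, GIF1, D14a and IRL were chosen after their values were seen.

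Alternatives were another pseudocount (0.1), other filters, 2 scalings of the values, a block for the replicate number, fits of only the 2 groups compared, each library left out in turn, a minimum log2 change of 1, and, for lists, camera with estimated correlation and fry. The procedure was tested on simulated data in 5 simulations per comparison. In each, 200 loci in all were changed, each by a factor of 1.5, 2 or 4 drawn at random. For low nitrogen in the division zone it recovered 8.55% of 2-fold and 77.9% of 4-fold changes with 6.19% false calls. The values were 9.24% and 72.5% with 7.10% in the elongation zone, and 5.71% and 69.4% with 6.82% between zones at high nitrogen. Recovery of 1.5-fold changes was 0%, 0.75% and 0.28% in the same order. Unchanged loci had the same mean and spread in all simulated libraries. In the data far more loci were called and HN elongation replicates spread more, so these rates do not carry over. Depth relative to HN division replicate 1, estimated from the steps between low values, was lowest in HN elongation replicate 2 (0.764) and highest in LN division replicate 1 (1.25); only 13.9 to 19.3% of the low values compared fell in step, so these depths are rough, and absolute depth is unknown. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.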

Results

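RNA was sequenced from leaf 6 of maize inbred line B73 grown in hydroponic culture. The tissues were the division zone at the leaf base, where cells divide, and the elongation zone above it, where they lengthen. Plants received high nitrogen (HN, 4 mM) or low nitrogen (LN, 0.04 mM). Each of the 4 combinations of supply and zone had 2 libraries, 8 in all, and the labels describe 2 biological replicates per tissue. The series asks how nitrogen shortage slows leaf growth and whether gibberellin synthesis takes part. The deposited table lists FPKM for 43110 loci, of which 24706 had a group mean of at least 1 FPKM and were tested. Sums per library ran from 652957 to 1113553 FPKM, and loci at 1 FPKM or more from 21136 to 22119. Read numbers were not used here, and the step between low values gave rough relative depths of 0.764 to 1.25, with HN division replicate 1 set to 1 and 13.9 to 19.3% of low values in step in the others. Levels are FPKM as mean ± SD with n = 2 libraries per group, positions are on B73 RefGen_v3, and changes are differences of log2(FPKM + 1), which understate changes of genes near or under 1 FPKM.

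Zone separated the libraries along the first principal component, which held 63.0% of the variance, and nitrogen supply separated them within each zone along the second (18.3%). The HN elongation libraries lay farthest apart within a group. Their Pearson correlation across loci was 0.945, against 0.974, 0.971 and 0.965 in the HN division, LN division and LN elongation groups, with loci not being independent replicates. The median SD between replicates was 0.27 in the HN elongation group on the log2 scale and 0.12, 0.15 and 0.10 in the others. HN elongation replicate 2 was higher than replicate 1 by a median of 0.98 for core histone, 0.71 for cytosolic ribosomal protein and 0.59 for photosystem genes. For low nitrogen in the elongation zone, values without it are also given for the histone, replication, ribosomal protein, photosystem and C4 lists. For most other lists, among them those that rose, values are given only with that library.

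**Figure D1:**
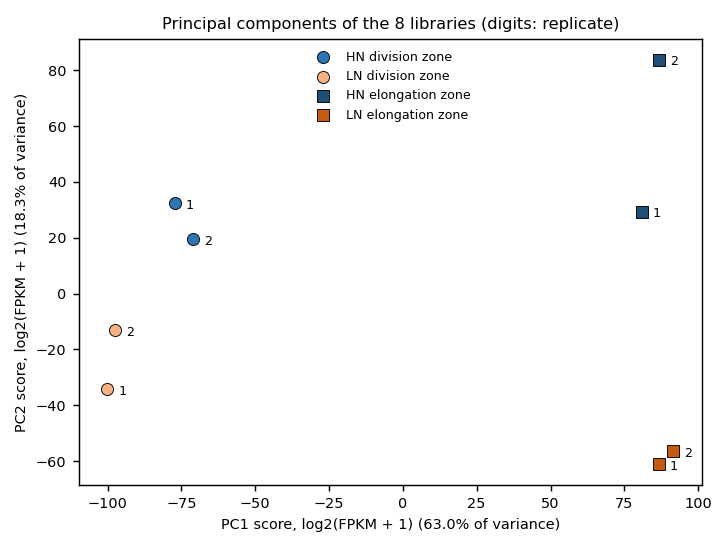
Scores of the 8 libraries on the first 2 principal components of log2(FPKM + 1), one point per library with its replicate digit. The components held 63.0% and 18.3% of the variance; division and elongation libraries lie at opposite ends of the first.

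The zones were compared at high nitrogen as a reference for the change from dividing to lengthening tissue. Most of the mitosis, replication and histone genes tested were lower in the elongation zone, while most aquaporin, expansin, primary wall cellulose synthase and photosystem genes were higher, and 0 of 3 secondary wall cellulose synthases were called. The plasma membrane aquaporins PIP2-3 and PIP2-4 went from 1.30 ± 0.0785 to 125 ± 50.4 FPKM and from 5.95 ± 0.217 to 324 ± 130.5 FPKM (log2 changes 5.72 and 5.49). The tonoplast aquaporin TIP2-1 rose by 5.39, from 0.722 ± 0.190 to 76.4 ± 40.8 FPKM. GIF1, a transcriptional coactivator that works with growth-regulating factors, fell from 22.7 ± 1.503 to 0.749 ± 0.592 FPKM (-3.80, adjusted p = 0.000214). ZCN3, of the FT and TFL1 family, fell from 24.4 ± 8.92 to 0.466 ± 0.659 FPKM (-4.14). A histone H4 locus named H4C7 (XLOC_035000), which shares its span with another locus, was 55.4 and 17.9 FPKM in the HN division libraries and listed at or near 0 in both HN elongation libraries.

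Of 19 mitosis and cytokinesis genes 15 fell and 2 rose (median -2.26). They included the cyclin cyc3, from 34.5 ± 1.11 to 3.01 ± 0.0793 FPKM, and the kinesin-related krp13, from 51.5 ± 1.87 to 3.50 ± 0.0863 FPKM. DNA replication genes fell at 14 of 15 loci, core histones at 25 of 27 and growth-regulating factors with their GIF partners at 14 of 20, with medians of -1.79, -1.48 and -1.75. Most of the histone loci carry the name H4C7 or H3C2, so here and below they may not be independent. In other lists too some loci share a gene identifier or name, such as GRF13, GRF8, psad1, lhcb7, CAB-M9 and GLN2. Counts and list p values of those lists may therefore also overstate the evidence. MCM6 and MCM7, subunits of the replicative helicase, dropped by 2.22 and 2.25. The calls of the lists for mitosis, DNA replication, histones and growth-regulating factors were lost at adjusted p = 0.420, 0.259, 0.515 and 0.504 with an estimated correlation. Aquaporins rose at 15 of 21 loci and fell at 1, expansins rose at 9 of 11, primary wall cellulose synthases at 6 of 8 and proton pumps at 4 of 6. The beta-expansin expB6 went from 1.69 ± 0.126 to 49.7 ± 4.42 FPKM, the xyloglucan-modifying xth1 from 2.93 ± 0.853 to 122 ± 8.81 FPKM and CesA-4 from 15.1 ± 1.89 to 75.7 ± 7.24 FPKM. For aquaporins, expansins, primary wall cellulose synthases and proton pumps the calls ended at adjusted p = 0.504 in each list with an estimated correlation. Photosystem and light harvesting genes rose at 14 of 16 loci (median 3.12) and C4 and Calvin cycle genes, markers of mature blade, at 7 of 7 (2.51), with adjusted p = 0.504 and 0.226 with an estimated correlation. PEPC1, the first carboxylase of C4 photosynthesis, went from 3.61 ± 1.05 to 53.1 ± 3.60 FPKM. Adjusted over the list alone, 15 mitosis, 15 replication, 27 histone and 16 growth-regulating factor loci fell, and 16 aquaporin, 9 expansin, 7 cellulose synthase, 4 proton pump, 14 photosystem and 7 C4 loci rose.

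Between zones 5453 loci were higher and 4855 lower in the elongation zone at high nitrogen (limma, BH-adjusted p under 0.05), and 6473 were higher and 5534 lower at low nitrogen. Of the 31 lists with at least 3 tested members, 13 were called at high nitrogen by camera with a preset correlation of 0.01, and 0 with an estimated one. Camera with an estimated correlation had 3 lists at an unadjusted p under 0.05, and fry called 21. The count at high nitrogen was 6143 and 6288 without HN division replicate 1 and 2, and 6714 with the 2 groups fitted alone. Scaling all libraries to an equal total moved the median of all loci by -0.20 and made 41.0% of called loci higher in place of 52.9%. Without HN elongation replicate 2, 27 histone loci fell and 15 photosystem loci rose, with medians of -2.05 and 2.82. Without HN division replicate 1 limma called 4 histone loci, and without replicate 2 it called 9 aquaporins.

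In the division zone, 4 of 7 C4 and Calvin cycle, 2 of 16 photosystem and 5 of 13 nitrogen assimilation loci fell under low nitrogen. Rises were called at 7 of 20 growth-regulating factor, 7 of 38 auxin and 5 of 16 TIFY loci. The largest fall among named genes was in HB, a hemoglobin (chromosome 9, 145596856 to 145598153), from 28.8 ± 2.25 FPKM at high to 0.568 ± 0.154 FPKM at low nitrogen (log2 change -4.25 ± 0.16 SE, adjusted p = 0.000249). The lipoxygenase lox1 fell from 55.2 ± 18.4 to 1.95 ± 0.698 FPKM (-4.23) and the polyamine oxidase pao1 from 58.7 ± 11.6 to 5.05 ± 0.396 FPKM (-3.29). The transcription factors LOB14, of the lateral organ boundaries family, and GLK44, of the G2-like family, fell by 2.93 and 2.64. The largest rises were in the transcription factor bHLH116, from 0.0283 ± 0.0400 to 6.78 ± 0.776 FPKM (2.92), TIFY25 (2.35), the YABBY factor yab14 (2.26), TIFY4 (1.91) and HB2 (1.80). YABBY factors are known for setting leaf polarity. In each gene named by the size of its change, both libraries of one group lay above both of the other.

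Growth-regulating factors and their GIF partners rose at 7 of 20 loci and fell at 0, with 13 not called (median 0.89, camera adjusted p = 7.57e-07). GRF11 went from 0.928 ± 0.166 to 5.37 ± 1.66 FPKM, GRF12 from 9.68 ± 0.436 to 27.0 ± 5.67 FPKM and GRF1 (GRMZM2G034876) from 8.15 ± 1.84 to 23.5 ± 4.10 FPKM. GIF1, picked out here after its values were seen, rose 3.32-fold, from 22.7 ± 1.503 to 75.2 ± 13.5 FPKM (adjusted p = 0.0320). Auxin genes rose at 7 of 38 loci with 0 falls (median 0.24, camera adjusted p = 0.000207), among them AUX1, from 2.68 ± 0.601 to 6.52 ± 0.518 FPKM, and the efflux carrier PIN1d, from 9.03 ± 0.725 to 16.8 ± 0.425 FPKM. Jasmonate genes rose at 9 of 33 loci and fell at 2 (median 0.39, camera adjusted p = 9.03e-05). Of the 9 that rose, 5 were TIFY genes, a family that includes the JAZ repressors of jasmonate signalling, and the falls were in the lipoxygenases lox1 and lox6. TIFY28 went from 0.185 ± 0.0634 to 2.97 ± 0.822 FPKM and TIFY9 from 0.0558 ± 0.00349 to 2.43 ± 0.602 FPKM, while TIFY20 was listed at 0 in both HN division libraries and at 1.61 and 2.95 FPKM in the LN division libraries. The growth-regulating factor, auxin and jasmonate lists had adjusted p = 0.520, 0.310 and 0.6504 by camera with an estimated correlation, so they were not called under it. That setting called 0 lists in every comparison, so it does not tell these lists from others. Of 10000 random lists matched on span and level, 0, 9 and 0 lay at or above their medians. Such random lists lack the correlation between members of a list. With p values adjusted over the list alone, 13 growth-regulating factor, 12 auxin and 11 jasmonate loci rose and 3 jasmonate loci fell.

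C4 and Calvin cycle genes fell at 4 of 7 loci (median -1.09), and all 7 lay below 0. The Rubisco small subunit loci RBCS (XLOC_023187) and rbcS went from 17.7 ± 1.93 to 3.01 ± 0.159 FPKM and from 12.98 ± 0.810 to 2.02 ± 0.0910 FPKM. Photosystem genes fell at 2 of 16 loci (median -0.96), in psbs1, which dissipates excess light energy, from 10.5 ± 0.464 to 2.82 ± 0.727 FPKM, and in the photosystem I subunit PSAH. Nitrogen assimilation genes fell at 5 of 13 loci and rose at 0 (median -0.79). NIR, nitrite reductase, went from 11.2 ± 1.91 to 3.66 ± 0.388 FPKM, a glutamine synthetase locus named GLN2 (XLOC_009297) from 34.5 ± 0.0148 to 12.6 ± 0.788 FPKM and GDH1, glutamate dehydrogenase, from 17.9 ± 0.644 to 8.54 ± 0.575 FPKM. Proton pumps fell at 2 of 6 loci (median -0.75), with the plasma membrane ATPase pma1 going from 18.8 ± 2.78 to 7.04 ± 0.0704 FPKM. Cytosolic ribosomal proteins had a median of -0.65, with 1 call, rpl19, among 32 loci. Random lists matched to them on span and level had a median of -0.42, and 227 of 10000 lay at or below the list. Camera with the preset correlation called these lists lower than other genes, at adjusted p = 7.57e-07 for C4, 9.03e-05 for photosystem, 0.00414 for nitrogen assimilation, 0.00204 for proton pump and 7.57e-07 for ribosomal genes. These calls ended at adjusted p = 0.161, 0.626, 0.520, 0.520 and 0.6504 with an estimated correlation, in the same order. When adjusted over the list alone, 7, 6, 7, 5 and 7 of their loci fell, and 1 nitrogen assimilation locus rose.

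Cell cycle lists showed few calls in the division zone. Of 19 mitosis genes 1 rose, cyclin11, from 9.98 ± 1.51 to 30.3 ± 5.25 FPKM, and the list's median was 0.03. The D-type cyclin cycD4 went from 8.48 ± 0.714 to 20.7 ± 3.14 FPKM (adjusted p = 0.0334). In limma, 0 of 15 DNA replication and 0 of 27 histone loci were called, also when adjusted over the list alone, with medians of 0.13 and 0.23 and with 1 and 0 loci at an unadjusted p under 0.05. Random lists matched on span and level had medians of -0.09 and -0.28, and 458 and 11 of 10000 lay at or above the lists. Type-A response regulators, which cytokinin induces and which dampen its signal, accounted for the 3 calls among 26 cytokinin loci. RR5 (GRMZM6G980248) went from 21.6 ± 5.65 to 6.32 ± 0.631 FPKM, RR5 (GRMZM2G156019) from 10.04 ± 1.89 to 3.99 ± 0.828 FPKM and RR6 from 3.93 ± 0.174 to 1.68 ± 0.297 FPKM. Wall genes gave 1 fall among 8 primary wall cellulose synthases, CesA-7, from 18.9 ± 1.38 to 7.57 ± 0.0454 FPKM, and 1 among 11 expansins, expB6, from 1.69 ± 0.126 to 0.0944 ± 0.0686 FPKM. The cellulose synthase list had a median of -0.33 (camera adjusted p = 0.0428), and adjusted p = 0.6504 with an estimated correlation. Its median was close to that of random lists matched on span and level (-0.26), of which 3380 of 10000 lay at or below it. Adjusted over the list alone, 1 mitosis, 2 D-type cyclin and 2 cytokinin loci rose and 4 cytokinin, 2 cellulose synthase and 1 expansin loci fell, with 3 expansins rising.

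In all, 448 loci rose and 809 fell under low nitrogen in the division zone (limma, BH-adjusted p under 0.05), 998 of them meeting the level and separation conditions for naming and 146 of those carrying a gene name. With 2 libraries per group, p values rested on a spread pooled over the 4 groups. The median SD was 0.12 and 0.15 in the HN and LN division groups and 0.27 in HN elongation. Pooling thus tended to overstate the spread of this comparison and to lower its counts of called loci. The counts of the division and elongation zones therefore do not rank the strength of their responses. The count was 63 and 66 without HN division replicate 1 and 2, 135 and 98 without the LN division, 285 and 282 without the LN elongation and 3560 and 3553 without the HN elongation replicates. The balance of directions turned without LN division replicate 1 (94 higher, 41 lower) and replicate 2 (64 higher, 34 lower). Without HN division replicate 1, limma called 0 growth-regulating factor, 0 auxin, 0 nitrogen assimilation, 1 jasmonate and 1 C4 loci. The total was 1977 with the 2 division groups fitted alone, and 2076 after scaling to equal totals, which moved the median of all loci by 0.15 and made 61.2% of called loci higher in place of 35.6%.

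In the elongation zone, most of the histone, replication, ribosomal protein, photosystem and C4 loci tested fell under low nitrogen. So did 6 of 13 nitrogen assimilation loci. Rises were called at 5 of 8 primary wall cellulose synthase, 6 of 38 auxin and 6 of 17 senescence and autophagy genes. The largest falls among named genes were in lox1, from 345.8 ± 30.4 to 15.3 ± 5.08 FPKM (log2 change -4.45 ± 0.31 SE, adjusted p = 0.00207), and in D14a, named for the strigolactone receptor, from 40.01 ± 4.32 to 1.45 ± 0.177 FPKM (-4.06). Polyamine oxidase pao1 fell from 1076 ± 440.2 to 86.5 ± 6.48 FPKM (-3.56), kin1 fell by 3.38, and the hemoglobin HB was 9.18 and 10.2 FPKM in the HN and listed at 0 in both LN libraries. The largest rises included see2b, a vacuolar processing enzyme gene induced in senescing leaves, from 23.9 ± 0.0157 to 116 ± 19.3 FPKM (2.23). CER1 (GRMZM2G066578), of a family that makes wax alkanes, went from 2.27 ± 0.312 to 16.1 ± 1.63 FPKM (2.39), NF-YA13, a subunit of a CCAAT-binding factor, from 1.63 ± 1.24 to 11.3 ± 1.34 FPKM (2.31) and ZHD13, a zinc finger homeodomain factor, from 4.95 ± 3.26 to 26.1 ± 4.91 FPKM (2.29). CslF6-1 (XLOC_008499), of the family that makes mixed-linkage glucan, was listed at 0 in both HN and at 3.05 and 22.9 FPKM in the LN libraries, and shares its span with another locus.

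Core histones fell at 26 of 27 loci (median -2.12) and DNA replication genes at 9 of 15 (-1.05), with 0 and 0 rising. Most of the histone loci share a name with others of the list, so their count and list p values may overstate the evidence. The histone his2b5 went from 439 ± 202 FPKM to 67.7 and 69.3 FPKM in the LN libraries, RNRS1, a ribonucleotide reductase small subunit, from 55.8 ± 23.2 to 10.9 ± 2.87 FPKM and MCM6 from 8.15 ± 0.488 to 3.27 ± 0.880 FPKM. Cytosolic ribosomal proteins fell at 31 of 32 loci (median -1.71), with RP-P0 going from 763 ± 145 to 179 ± 19.4 FPKM and rps13 from 324 ± 86.4 to 82.2 ± 4.99 FPKM. Photosystem genes fell at 13 of 16 loci (median -1.63), such as the light-harvesting gene cab-m1, from 677 ± 173 to 111 ± 66.0 FPKM. C4 and Calvin cycle genes fell at 6 of 7 loci (-1.96), with PEPC1 going from 53.1 ± 3.60 to 6.18 ± 0.454 FPKM and rca1, Rubisco activase, from 11.6 ± 1.97 to 2.24 ± 0.714 FPKM. Without HN elongation replicate 2, which read high for several of these groups, 23 histone, 10 replication, 25 ribosomal, 6 photosystem and 7 C4 loci fell, with medians of -1.59, -0.99, -1.31, -1.27 and -2.13. Random lists matched on span and level had medians of -0.91 for histone, -0.92 for ribosomal protein and -0.45 for photosystem genes. For replication and C4 genes they had -0.06 and -0.10. Of 10000 random lists each, 0, 0, 0, 1 and 0 lay at or below the gene list, in the same order. In another draw those for ribosomal protein genes reached -1.72, and random lists lack the correlation between members. By camera, the histone, replication, ribosomal, photosystem and C4 lists had adjusted p = 0.460, 0.330, 0.460, 0.460 and 0.181 with an estimated correlation. With the preset one they had 9.45e-13, 1.52e-05, 7.95e-16, 7.28e-07 and 1.46e-06. If adjusted over the list alone, 26, 10, 32, 13 and 7 of their loci fell.

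Mitosis genes went both ways, with 4 rises and 2 falls among 19 loci (median 0.15): cyclin4 went from 25.2 ± 0.994 to 43.5 ± 0.330 FPKM and the kinesin-related krp11 from 6.24 ± 0.244 to 4.07 ± 0.676 FPKM. Nitrogen assimilation genes fell at 6 of 13 loci (median -0.57, camera adjusted p = 0.00424), among them NNR1, nitrate reductase, from 14.5 ± 5.604 to 2.72 ± 1.69 FPKM, NIR from 29.2 ± 5.09 to 9.88 ± 4.10 FPKM and GLN2 (XLOC_009297) from 106 ± 0.329 to 32.1 ± 2.48 FPKM. Cytokinin genes rose at 8 and fell at 6 of 26 loci. The response regulators RR7 and RR6 and the regulator gene crr2 fell by 2.096, 1.57 and 1.92, RR7 going from 19.0 ± 4.25 to 3.63 ± 0.394 FPKM. Of the 8 cytokinin loci that rose, 5 carry the name HK of the histidine kinase receptors, such as HK1, from 4.14 ± 0.458 to 7.78 ± 0.649 FPKM, which was picked out after its values were seen. Primary wall cellulose synthases rose at 5 of 8 loci (median 0.61, camera adjusted p = 0.000796), with CesA-1 going from 53.5 ± 1.62 to 106 ± 2.65 FPKM and CesA-7 from 48.6 ± 8.07 to 76.6 ± 1.23 FPKM. Of the 3 secondary wall cellulose synthases 2 rose, CesA12 from 5.92 ± 0.824 to 14.9 ± 0.529 FPKM and CesA13 from 0.626 ± 0.145 to 1.81 ± 0.156 FPKM. Auxin genes rose at 6 of 38 loci (median 0.32, camera adjusted p = 0.00142), AUX1 going from 1.25 ± 0.399 to 7.12 ± 0.0623 FPKM. Senescence and autophagy genes rose at 6 of 17 loci (median 0.46, camera adjusted p = 0.00142), among them ATG3 and atg9, whose proteins act in autophagosome formation. The nitrogen assimilation, cellulose synthase, auxin and senescence calls were lost, at adjusted p = 0.460, 0.460, 0.330 and 0.460 with an estimated correlation. Adjusted over the list alone, 8 primary and 2 secondary wall cellulose synthase, 6 auxin, 11 senescence, 5 mitosis and 8 cytokinin loci rose, and 6 nitrogen assimilation, 2 mitosis and 7 cytokinin loci fell. Among 20 growth-regulating factor loci and 11 expansins limma called 0 and had 3 and 4 at an unadjusted p under 0.05, with medians of 0.27 and -0.08, and adjusted over the list alone 0 growth-regulating factors and 1 expansin rose and 2 expansins fell.

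In total, 2437 loci rose and 3094 fell under low nitrogen in the elongation zone (limma, BH-adjusted p under 0.05), 4444 meeting the conditions for naming, 520 of these with a name. The spread behind these p values was pooled over all groups, with a median SD of 0.27 in HN elongation and 0.10 to 0.15 in the others. Pooling thus understated the spread of this comparison, so its p values tend to be too low and its counts of called loci too high. The count was 42 (14 higher, 28 lower; 7146 at an unadjusted p under 0.05) with the 2 elongation groups fitted alone, and 516 and 1184 without LN elongation replicate 1 and 2, 3031 and 3034 without the HN division replicates, 3512 and 3538 without the LN division replicates, 10197 without HN elongation replicate 1 and 4368 without its replicate 2. Scaling to equal totals called 8548 loci and moved the median of all loci by 0.38, with 77.5% of called loci higher in place of 44.1%, and median-of-ratios scaling gave 29.9%. Limma called 0 histone and 2 replication loci without LN elongation replicate 2, and 0 ribosomal protein, 0 cellulose synthase and 2 photosystem loci without replicate 1.

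**Figure D2:**
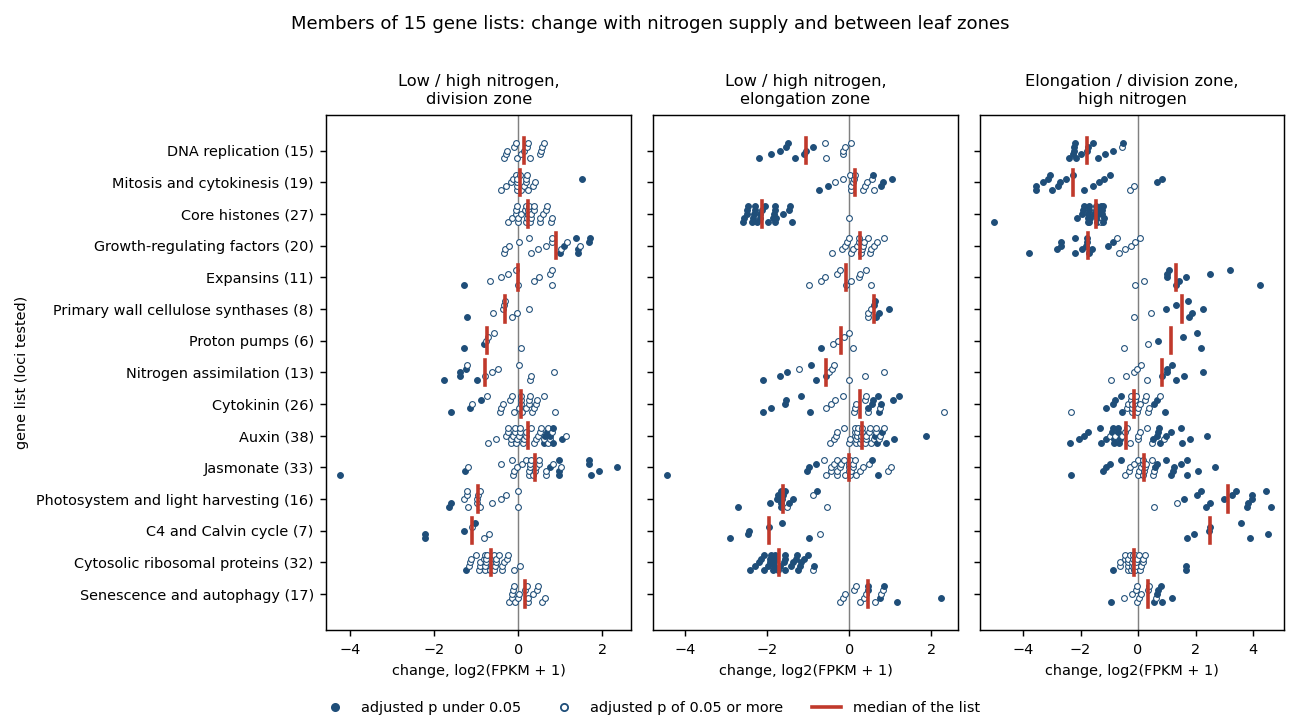
Change of each tested locus of 15 gene lists in log2(FPKM + 1) with low nitrogen in the division zone (left) and elongation zone (middle), and from division to elongation zone at high nitrogen (right). Each point is a locus, filled where adjusted p was under 0.05, and red bars are list medians; core histones had a median of -2.12 in the middle panel and 0.23 in the left one.

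Gibberellin biosynthesis, the subject of the series, was represented by 3 tested loci. The list held only these and the untested CPPS2 and ga3ox2, so other steps of the pathway were not examined. The first committed step is catalysed by ent-copalyl diphosphate synthase, encoded by an1 (chromosome 1, 241277428 to 241285679). In the division zone an1 was 1.34 ± 0.0243 FPKM at high and 2.12 ± 0.661 FPKM at low nitrogen (log2 change 0.40 ± 0.23 SE, adjusted p = 0.350), and in the elongation zone 0.390 ± 0.311 and 0.235 ± 0.0123 FPKM (-0.15, adjusted p = 0.656). Dwarf1 (chromosome 3, 10455337 to 10457618), the gibberellin 3-oxidase that makes bioactive forms, was 3.06 ± 0.664 and 6.02 ± 1.36 FPKM in the division zone (0.78, adjusted p = 0.206) and 0.897 ± 0.767 and 1.19 ± 0.434 FPKM in the elongation zone (0.25, adjusted p = 0.595). CYP88A1 (chromosome 9, 26725936 to 26729883), ent-kaurenoic acid oxidase, fell in the elongation zone from 1.76 ± 0.0799 to 0.660 ± 0.109 FPKM, a factor of 2.67 (-0.74 ± 0.17 SE, adjusted p = 0.0289). In the division zone CYP88A1 was 1.05 ± 0.255 and 0.520 ± 0.0598 FPKM (-0.43, adjusted p = 0.1999). The difference between zones in its nitrogen response was not called (adjusted p = 0.499). At high nitrogen an1 and Dwarf1 fell from division to elongation zone by 0.77 and 1.15 (adjusted p = 0.0346 and 0.0275). CPPS2, another copalyl diphosphate synthase gene, and ga3ox2 were listed at 0 in 7 of 8 libraries each, with 0.0198 FPKM in LN elongation replicate 2 and 0.0444 FPKM in LN elongation replicate 1. The DELLA gene d9, whose product represses gibberellin responses, fell in the elongation zone from 27.5 ± 4.28 to 16.3 ± 1.36 FPKM (adjusted p = 0.0484), and D8 was 107 ± 51.2 and 71.6 ± 6.42 FPKM there (adjusted p = 0.304). By limma adjusted over the list alone, 1 biosynthesis and 1 signalling locus fell in the elongation zone and 0 of each in the division zone. As a list, biosynthesis had medians of 0.40 and -0.15 in the division and elongation zone, with camera adjusted p = 0.687 and 0.563. The calls of CYP88A1 and d9 in the elongation zone were lost without HN elongation replicate 2, without LN elongation replicate 1 or 2 and after scaling to equal totals, and that of d9 also without either HN division replicate. Those of an1 and Dwarf1 between zones were lost without either HN division replicate. Gibberellin catabolism genes had no usable names in the reference table and were not analysed here.

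**Figure D3:**
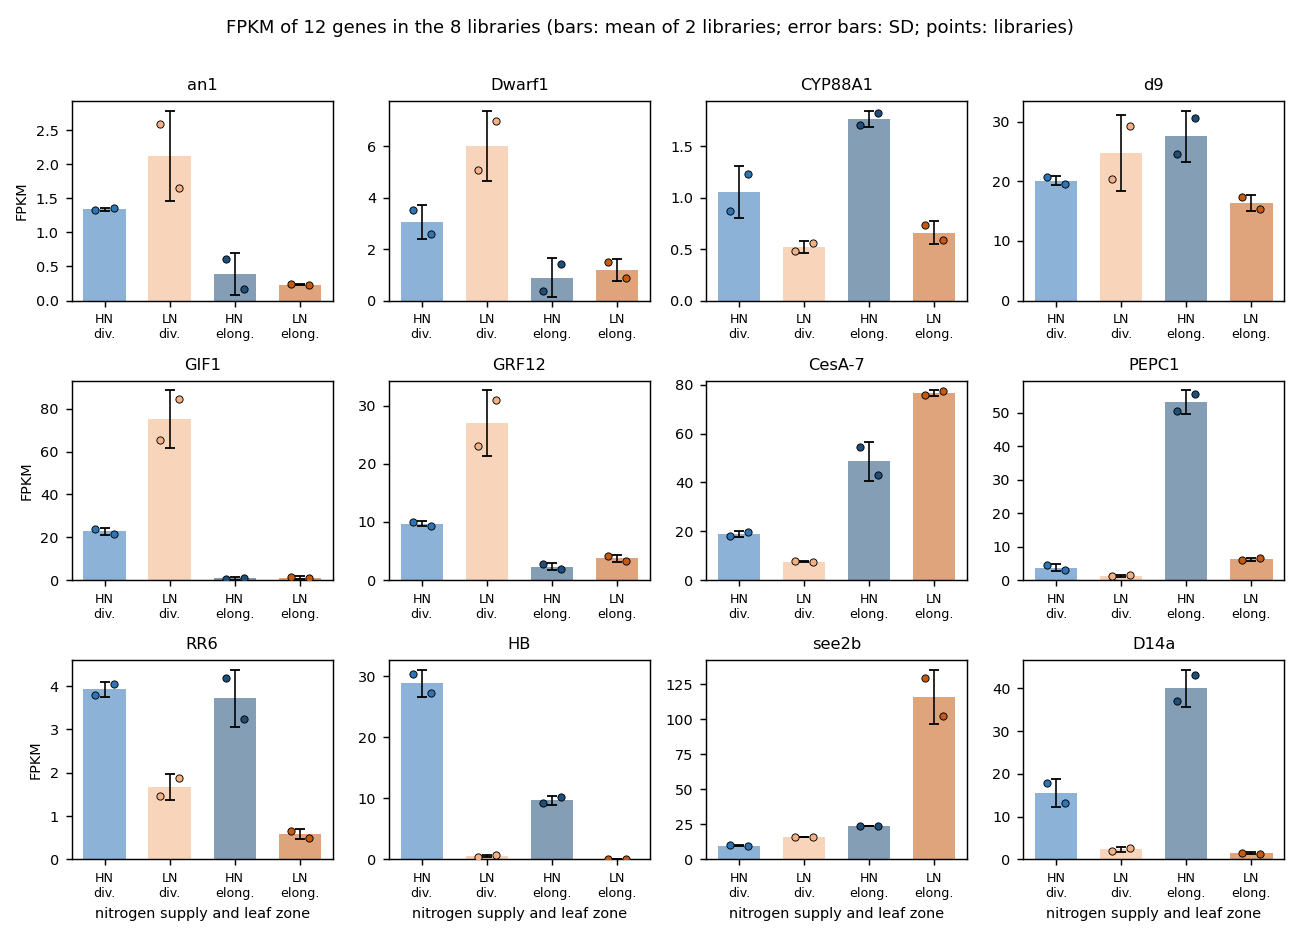
FPKM of 12 genes in the 8 libraries, with bars for the mean of 2 libraries, error bars for the SD and points for libraries, for high (HN) and low nitrogen (LN) in the division and elongation zones. CYP88A1 was 1.76 FPKM in the HN and 0.660 FPKM in the LN elongation zone, and GIF1 22.7 FPKM in the HN and 75.2 FPKM in the LN division zone.

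The nitrogen responses of the zones were compared by the overlap of their calls and by an interaction term. The contrasts share no library, but their tests share a spread pooled over all libraries, which the expectation for independent lists leaves out. Falls overlapped most: 574 loci fell in both zones, where independent lists would share 101, and 146 rose in both, where independence gives 44.2. Of the 733 loci called in both zones, 720 changed in the same direction and 13 in opposite directions. Among genes that fell in both zones were lox1, lox6, pao1, HB, D14a, NIR, RR6 and the Rubisco small subunit genes RBCS and rbcS, while AUX1 and NF-YA11 rose in both. Across the 24706 loci the changes correlated with r = 0.42, with loci not being independent replicates. The interaction called 70 loci, 32 with a higher and 38 with a lower response in the elongation zone, and 61 met the conditions for naming, 10 of these with a name. CesA-7 (chromosome 7, 37037007 to 37042784) fell in the division zone and rose in the elongation zone, with a difference between responses of 1.87 ± 0.22 SE (adjusted p = 0.0376). CER1 (GRMZM2G066578) and IRL, an isoflavone reductase-like gene, differed by 2.74 and 1.81, and IRL went from 6.41 ± 0.526 to 1.75 ± 0.233 FPKM in the division zone and was 27.3 ± 2.14 and 35.7 ± 4.00 FPKM in the elongation zone. In the other direction were bHLH116 (-2.66), SLD5, a subunit of the GINS replication complex that shares its span with another locus (-2.44), and nfd106, a chromatin assembly gene (-2.23). The last went from 341 ± 34.1 to 403 ± 18.6 FPKM in the division zone and from 84.6 ± 16.8 to 20.4 ± 0.840 FPKM in the elongation zone. As lists, core histones (median difference -2.39), DNA replication (-1.23) and ribosomal protein genes (-1.02) responded lower in the elongation zone and primary wall cellulose synthases higher (0.96), at camera adjusted p = 1.70e-18, 4.11e-07, 5.11e-10 and 3.77e-06. These ended at adjusted p = 0.578, 0.487, 0.578 and 0.487 with an estimated correlation. Adjusted over the list alone, the interaction was called lower at 26 histone, 10 replication and 0 ribosomal loci and higher at 5 cellulose synthase loci. Random lists matched on span and level had a median of -0.57 for ribosomal protein genes, and without HN elongation replicate 2 the medians were -1.87 for histones, -0.99 for replication and -0.69 for ribosomal protein genes. The split by direction depended on single libraries, with 20 higher and 5 lower and 20 and 8 without HN division replicate 1 and 2, 7 and 47 and 4 and 26 without the LN division, and 51 and 12 and 55 and 13 without the LN elongation replicates. The interaction count was 3746 without HN elongation replicate 1 and 63 without replicate 2, 25 and 28 without the HN division replicates, 30 without LN division replicate 2, 152 with no filter on low values and 244 after scaling to equal totals, with 4454 loci at an unadjusted p under 0.05. Without HN elongation replicate 1 camera called 8 lists in place of 13, and the call of CesA-7 was lost without any 1 of the division or LN elongation libraries.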

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

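The tests on the division zone pattern and those that set the elongation zone pattern against the zone change were chosen only after the result was seen; the tests on locus span and on the second HN elongation library were written before theirs.

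The nitrogen response differed between zones, by the interaction term of the limma model, at 70 loci. Named genes among them, with the elongation response minus the division response, were CER1 (GRMZM2G066578) at 2.74, CesA-7 at 1.87, IRL at 1.81, bHLH116 at -2.66, SLD5 at -2.44 and nfd106 at -2.23. By camera with the preset correlation, 13 lists differed. Median differences were -2.39 for core histones, -1.23 for DNA replication, -1.22 for benzoxazinoids, -1.02 for cytosolic ribosomal proteins, -0.55 for photosystem and light harvesting (-0.26 without HN elongation replicate 2), -0.54 for growth-regulating factors, -0.49 for jasmonate and -0.30 for C4 and Calvin cycle genes. They were 1.01 for secondary and 0.96 for primary wall cellulose synthases, 0.76 for xyloglucan, cellulose and pectin remodelling enzymes, 0.34 for lignin and phenylpropanoid and 0.32 for senescence and autophagy genes. For photosystem and C4 genes the differences were no larger than is common in loci of like span and level, as 1906 and 2140 of 10000 matched random lists lay at or below them, with medians of -0.37 and -0.12. With an estimated correlation camera called 0 lists and had 2 at an unadjusted p under 0.05, and fry called 4.

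In the division zone, 2 of 16 photosystem and 4 of 7 C4 loci fell and 7 of 20 growth-regulating factor loci rose under low nitrogen. Some photosystem and growth-regulating factor loci share a gene identifier, so they are not independent genes. By camera with an estimated correlation the lists had adjusted p = 0.626, 0.161 and 0.520. Each list's median went against its change from division to elongation zone. A candidate explanation is that the LN sample lay earlier on that path, with all lists moving in proportion; mitosis genes would then have a median change of 0.698, and the observed one was 0.0287 with a spread of 0.0557. Core histones do not speak against it, as their median of 0.225, where 0.456 was predicted, lay above that of random lists matched on span and level (-0.28), of which 11 of 10000 were at or above it. Scaling by library totals does not account for it either, since under both other scalings the photosystem median was -0.84 or lower and the growth-regulating factor median 0.88 or higher. A delay limited to leaf maturation genes, as a response to low nitrogen, may stay as a hypothesis and was not tested apart from where the tissue was taken.

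In the elongation zone, 26 of 27 core histone, 31 of 32 ribosomal protein and 13 of 16 photosystem genes fell (23, 25 and 6 without HN elongation replicate 2) and 5 of 8 primary wall cellulose synthases rose, at adjusted p = 0.460 in each list with an estimated correlation. If the LN sample lay further along the path from division to elongation, histones would fall and cellulose synthases rise along it, and their zone medians at high nitrogen were -1.48 and 1.53, as that explanation needs. DNA replication genes went with it (zone median -1.79, low nitrogen change -1.05). Mitosis genes (-2.26 and 0.15), growth-regulating factors (-1.75 and 0.27) and expansins (1.33 and -0.08) did not, so the lists did not move together along the path. Photosystem genes had a zone median of 3.12 (2.82 without HN elongation replicate 2), so a position further along the path could not account for their fall. A position less far along, which would lower them, was not tested, and histones, which it would raise, fell. Ribosomal protein genes had -0.15, and -0.49 without that library, which by itself does not decide for them. Higher readings of short loci in the HN libraries could account for part of the fall of ribosomal protein genes (median -1.71): 10000 random lists matched on span and level had a median of -0.92 and a lowest value of -1.72, and in another draw 0 of 10000 lay at or below the list, with a lowest of -1.70, while random loci can include ribosomal protein genes without a name. A response of these genes to low nitrogen itself stays open.

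HN elongation replicate 2 stood apart from replicate 1. The difference between them ran with locus span (Spearman correlation -0.308 across genes, which are not independent replicates), so higher readings of short loci in replicate 2 may explain part of it, though the LN division replicates gave -0.303 and HN division 0.232. A tissue position further along or less far along the leaf is argued against by a correlation of -0.0708 with the zone change at low nitrogen. That zone change came from plants of the other supply, which limits the test. The correlation with the zone change at high nitrogen was 0.177, but that change was computed from the same 2 libraries, so it does not decide. The correlation with the low nitrogen change in the division zone was -0.0221. It cannot decide on a different nitrogen state, because the elongation zone responded otherwise, with a core histone median of -2.12 against 0.23. On the second principal component replicate 2 scored 83.8 and replicate 1 29.3, against -61.1 and -56.4 in the LN elongation libraries. What made the span difference was not tested.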

How the results depend on the processing

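The other scalings, the filter on 2 libraries, the crossed replicate numbers and, for lists, the pseudocount were chosen only after the data were seen, and the remaining alternatives were planned. Low nitrogen in the division zone changed 1257 loci, and 2076 after scaling to equal library totals, 1977 with only the 2 groups compared and 775 with an absolute log2 change of at least 1. In the elongation zone the 5531 loci became 8548, 42 and 2818 under the same settings. Loci whose effect differs between zones numbered 70, 152 with no filter on low values and 244 after scaling to equal totals. Zone differences at high nitrogen (10308 loci) became 6714 with only the 2 groups compared and 5993 with the minimum change, and those at low nitrogen (12007) became 7460 with the minimum change. The cause of these moves was not tested, except that the minimum change drops loci by construction. Other settings, a pseudocount of 0.1, other filters and median-of-ratios scaling, left each of these counts within 1.5 times, apart from the one named.

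With the replicate number as a block, the counts were 506 in the division zone, 4245 in the elongation zone and 7 for the difference between zones, so the first and last fell by more than 1.5 times. The block stands for a shared number only: correlations of deviations between groups ran from -0.190 to 0.329. With numbers crossed in the low nitrogen groups or in the elongation groups, the block gave 447 and 317, 3582 and 3414, and 5 and 8 loci.

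Leaving out 1 library in turn, which for a lone remaining library assumes the spread of the other groups, gave 63 (without HN division replicate 1) to 3560 loci (without HN elongation replicate 1) in the division zone. It gave 516 (without LN elongation replicate 1) to 10197 in the elongation zone, 25 to 3746 for the difference between zones, 6143 to 12684 between zones at high and 8275 to 14403 at low nitrogen. The highest of each of these ranges came without HN elongation replicate 1. Lists called numbered 10 to 14, 11 to 12, 13 to 14 and, for the difference between zones, 8 to 15.

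Camera with an estimated correlation called 0 lists in the division zone, 0 in the elongation zone, 0 between zones at high nitrogen and 0 for the difference between zones, where the preset one called 11, 11, 13 and 13; lists at an unadjusted p under 0.05 numbered 2, 3, 3 and 2. Since the estimated correlation left 0 calls in each comparison, a call lost under it does not tell 1 list from another. Fry in place of camera called 7, 13, 21 and 4. Under the other settings run for lists the counts stayed within 1.5 times.

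Of the called values of named genes, 0 turned sign under any setting run. Calls were lost for 96 of 243 with only the 2 groups compared, 32 of 249 with the replicate block, 24 of 249 after scaling to equal totals, 13 without a filter, 12 with the other pseudocount, 4 with median-of-ratios scaling and 469 of 1991 without 1 library. TUBA2, not called in the elongation zone, went from -0.08 to 0.39 after scaling to equal totals, which raised the median of all loci by 0.38. DESeq2, limma-voom, RLE against TMM normalisation and filters on read counts were planned and not run, because the table holds no counts. Absolute depth is unknown, so the precision of low values could not be given.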

Other observations

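The counts for transcription factor families and the tests of tubulins, benzoxazinoids and plastid gene names were chosen only after the result was seen; the other lists were planned.

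NF-YA, the subunit that gives the NF-Y complex its sequence specificity, was looked at as a family after NF-YA13 was seen among the largest rises, by counts without a test of enrichment. Of 6 tested loci, 5 rose in the elongation zone, where 9.86% of all loci rose, and 1 rose in the division zone, and all 6 had changes above 0 in both zones. NF-YA11 went from 2.52 ± 1.13 to 13.8 ± 0.0768 FPKM in the elongation zone and from 1.70 ± 0.161 to 5.98 ± 0.332 FPKM in the division zone; loci named NF-YA4 are 2 neighbours on chromosome 1, so they are not independent. YABBY genes gave 3 tested loci, of which 2 rose with low nitrogen in the division zone and 3 fell from division to elongation zone at high nitrogen. Of 36 bHLH loci 7 rose and 1 fell in the division zone, with 2 and 2 in the elongation zone. Benzoxazinoid genes, which make defence compounds of grasses, fell at 7 and rose at 1 of 10 loci in the elongation zone (median -1.72, camera adjusted p = 2.80e-05), and without HN elongation replicate 2 fell at 6. CYP71C4 went from 137 ± 20.3 to 14.3 ± 3.70 FPKM and BX14 from 5.02 ± 1.90 to 0.596 ± 0.0843 FPKM. In the division zone 1 fell (median -0.57, camera adjusted p = 0.00445), and the list had adjusted p = 0.6504 in the division and 0.460 in the elongation zone with an estimated correlation.

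Laccase genes were among the 4 rises and 1 fall of 17 lignin and phenylpropanoid loci in the elongation zone (median 0.27, camera adjusted p = 0.316). Laccase-13 (GRMZM2G132169) went from 0.423 ± 0.0279 to 5.24 ± 1.43 FPKM. KNOX1 rose there from 8.49 ± 1.102 to 19.8 ± 1.66 FPKM, the call of 4 tested KNOX loci, and the meristem gene KN-1 was listed at 0 in 6 of 8 libraries. The small heat shock gene hsp18c fell in the elongation zone from 38.5 ± 21.8 to 10.7 ± 0.652 FPKM and HSP82 rose from 0.322 ± 0.127 to 1.07 ± 0.0358 FPKM, among 19 heat shock loci. Sucrose and starch genes fell at 3 of 20 loci, SPP2, sucrose-phosphate phosphatase, going from 3.01 ± 0.162 to 0.641 ± 0.286 FPKM. VP14, which catalyses a step of abscisic acid synthesis, went from 1.96 ± 0.229 to 0.461 ± 0.0707 FPKM, the fall among 8 abscisic acid loci, and ACO20, named as an ethylene-forming oxidase, from 3.04 ± 0.711 to 0.255 ± 0.0443 FPKM, 1 of 2 falls among 4 ethylene loci. Jasmonate genes rose at 2 and fell at 4 of 33 loci there, and aquaporins and proton pumps fell at 1 of 21 and 1 of 6. Cuticle and wax genes rose at 2, xyloglucan, cellulose and pectin remodelling enzymes at 2 and flavonoid genes at 1 of 9, 7 and 5 loci. Plastid gene names fell at 5 of 14 loci (median -0.79), with adjusted p = 0.460 with an estimated correlation. In the elongation zone limma called 0 of 15 tubulin, 0 of 2 brassinosteroid, 0 of 1 phosphate transporter and 0 of 1 nitrate transport loci. Of these, 1, 0, 0 and 0 had an unadjusted p under 0.05. Adjusted over the list alone, 5 lignin, 1 KNOX, 3 cuticle, 2 remodelling enzyme and 1 flavonoid loci rose and 9 benzoxazinoid, 6 sucrose and starch, 1 abscisic acid, 2 ethylene and 7 plastid loci fell.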
